A study of Mus musculus with 9 samples.

How the data were processed

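Muscle from male ICR mice, an outbred stock, was profiled by RNA sequencing of total RNA in 9 libraries. The labels give 3 groups of 3 libraries: vehicle-treated mice at 2 months (young vehicle 2, 3 and 4), vehicle-treated mice at 18 months (aged vehicle 1, 3 and 4), and 18-month mice given GW8510 at 2 mg/kg by intraperitoneal injection each day for 14 days (aged GW8510 1, 3 and 4). GW8510 is a benzenesulfonamide, per the series title, which names the p21-activated kinases as its partners. The labels do not name the muscle, give no time of day for tissue collection, and do not say that each library comes from a separate animal, so the p-values measure the spread between samples.

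The authors deposited 3 tables, 1 for each pair of groups, each with 55536 genes. Expected counts per gene and library were deposited without normalization, per the file headers and the values, of which 91.4% are whole numbers and the others carry fractions. The tables also hold the TPM values that the authors deposited per library, which were not used here. For each pair of groups the authors deposited a log2 ratio, a p-value and an adjusted p-value, with a mark for genes called significant. The submitters' processing notes name the mouse assembly GRCm38 and the tools CASAVA, HISAT2, StringTie, RSEM, DESeq2 and edgeR, with no versions or roles, and the notes do not say whether counting used strand or which gene annotation was used. All 55536 gene IDs were found in GENCODE M21, from which gene coordinates (GRCm38) and gene types were taken. A library's counts were identical in the 2 tables that hold it (largest difference 0). Dates stood in place of 27 gene symbols in a single table, and the symbols of the other tables were used.

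Counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr, which left 14384 genes, and 29661 genes had no count in any library. Scaling used TMM factors. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), with all 9 libraries in 1 fit and 1 mean per group, two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05 on the adjusted p. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of F. Levels are CPM, counts scaled by the TMM-adjusted library size, given as mean ± SD with n = 3 libraries per group. The 3 comparisons were aged vehicle over young vehicle, aged GW8510 over aged vehicle, and aged GW8510 over young vehicle. The design, the alternatives, the 38 gene lists and the rule for named genes were fixed before the data were examined.

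The genes named are, per comparison, those past the threshold with a mean of at least 1 CPM and no overlap between the libraries of the groups, the 10 with the most positive and the 10 with the most negative log2 fold change, leaving out clone-style symbols and pseudogenes. To these were added up to 4 members of each gene list with the smallest adjusted p among those past the threshold, and the p21-activated kinase family. Where under 10 genes passed, the 10 with the smallest p were taken instead, and these are said not to pass. A gene named in 1 comparison may be given in the others. Genes chosen after their values were seen are marked as such.

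The 38 gene lists cover energy metabolism, fibre type, ageing, stress and signalling, and markers of other cell types that a dissected muscle can hold. Of these, 36 had at least 5 tested members, and the markers of T and NK cells and of cartilage, bone and skin had fewer. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry. The estimated correlation was 0.796 for respiratory chain, 0.814 for ribosomal protein and 0.754 for collagen and matrix genes. For such lists the p at the preset correlation is too small, and members of the same sign are not independent. Members past the threshold were counted over all genes tested and adjusted over the list alone. Annotation terms from the deposited tables with 10 to 500 tested members were tested with 1-sided Fisher exact tests against the tested genes with an annotation. Each term was tested for higher and for lower genes apart, and the counts of tests include both. The analysis of age genes in the treatment comparison shares the aged vehicle libraries between both contrasts. Values without a treatment effect were therefore simulated 20 times with the fitted dispersions. The simulations took the measured group means, noise included, as the true means. Each aged vehicle library was also held out in turn.

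Library totals ran from 21718930 to 27437937. A floor of 3 counts corresponds to 0.109 to 0.138 CPM, depending on the library, and the floor covers counting error only. The common dispersion was 0.0812 with 3.88 prior degrees of freedom. On simulated counts for the real genes, with 200 changed genes drawn from those with a mean count of at least 50, the main test recovered 39 of 100 genes changed 2-fold and 95 of 100 changed 4-fold in the age comparison. The same test recovered 37 and 91 of 100 in the treatment comparison, and 28 and 94 of 100 for aged GW8510 over young vehicle. Between 6 and 7 unchanged genes were called in each. Simulations with these dispersions and the age means called 1291 genes with age on average, against 175 in the data. They took the measured means, noise included, as true, so this gap does not measure recovery. Recovery in the data was not measured and may be lower.

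The alternatives fixed beforehand were size factors computed as in DESeq2 (edgeR RLE), library totals with no TMM, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, no filter or a filter at 1 CPM, a fit on only the 6 libraries compared, the replicate number as a block, a fold change of at least 2, and leaving out each library in turn. Where this left a group with 2 libraries, the spread was still pooled over the other groups. A library outside the groups compared enters a comparison only through the pooled spread, the gene filter and the scaling. Alternatives added after seeing the data were DESeq2 on the 6 libraries with no filter, protein-coding genes only, term tests under the other settings, and list members without aged vehicle library 4. Tables were joined with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Near-identical copies can split reads in the deposited counts, so the levels of the Hspa1a and Hspa1b pair, Amy1, the zinc finger genes Zfp968 and Zfp973, Rpsa with its processed pseudogenes, and the clone-named genes are uncertain, as are overlapping and antisense genes.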

Results

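The data are expected gene counts from 9 muscle libraries. The young vehicle libraries held 26369977, 23405495 and 26489544 counts. The aged vehicle libraries held 27437937, 25465202 and 21718930, and the aged GW8510 libraries held 23372569, 23890250 and 22344065. The first principal component of the 1000 most variable genes carried 42.9% of the variance and placed the young libraries between -41.7 and -36.6 and the aged libraries between 2.52 and 45.8. The second component carried 15.6%. Aged vehicle library 4 stood apart from every other library, at 41.2 on the second component, and its mean correlation with the other libraries of its group was 0.942. In the other aged vehicle libraries this correlation was 0.958 and 0.956.

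**Figure D1:**
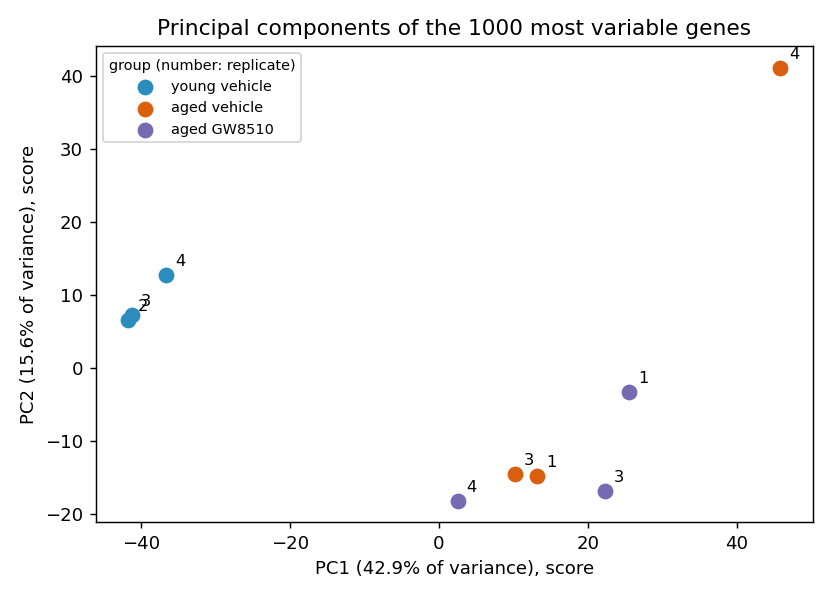
Scores of the 9 libraries on the first 2 principal components of the 1000 most variable genes (log2 CPM), with the share of variance on each axis, colour for the group and the number beside each point for the replicate. Aged vehicle library 4 lies at 45.8 on the first component and 41.2 on the second, away from the other aged libraries.

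The first comparison asked which transcripts differ between muscle of 18-month and 2-month vehicle-treated mice. Of 14384 genes tested, 75 rose and 100 fell with age (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Pseudogenes made up 13 of these 175 calls, against 404 of the 14384 genes tested. A difference in stock or collection time between the young and aged mice cannot be told apart from age here. The clock repressor gene Per2 rose 6.50-fold, to 15.2 ± 3.30 against 2.34 ± 0.774 CPM in the young (SD, n = 3 each), and Per3, its relative, rose 3.51-fold. Dnajb1, which encodes a co-chaperone induced by heat stress, fell 8.40-fold, with a log2 fold change of -3.07 (standard error 0.26). Fosb, a component of the AP-1 transcription factor, fell 30.9-fold, and the matrix glycoprotein gene Sparc fell 5.41-fold.

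Among the named genes, which leave out pseudogenes and clone-style symbols, the largest rise was in Tmem232, a transmembrane protein gene (ENSMUSG00000045036, chromosome 17 from 65255999 to 65540782, protein coding), at 21.9 ± 5.01 against 1.53 ± 0.457 CPM. Its log2 fold change was 3.84 with a standard error of 0.35 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00234). Among the 42 named genes past the threshold, Tmem232, Per2 (ENSMUSG00000055866, chromosome 1 from 91415982 to 91459324), Per3 (ENSMUSG00000028957, chromosome 4 from 151003652 to 151044665) and Dnajb1 (ENSMUSG00000005483, chromosome 8 from 83608193 to 83612653) were the 4 that also passed in each of the 9 fits that left out 1 library. With the replicate number as a block, Tmem232 still passed and Per2, Per3 and Dnajb1 did not. Other large rises were in Katnal2, a relative of the microtubule-severing katanins (9.32-fold), Rasd2, a small GTPase gene (6.94-fold), Nxpe3 (7.02-fold), Tal2, a basic helix-loop-helix factor (5.40-fold) and the amylase gene Amy1 (4.74-fold). The largest fall among the named genes was in Prnd, which encodes the prion-like protein doppel, at 0.152 ± 0.146 against 7.85 ± 6.08 CPM. The aged mean of Prnd lies close to the floor of 0.109 to 0.138 CPM, so the size of this fall is uncertain. Apold1, an endothelial early response gene, fell 12.6-fold, and Kl, which encodes the co-receptor klotho, fell 10.7-fold. The log2 fold change of Apold1 went from -3.66 to -2.81 without young vehicle library 2, and Apold1 passed in 1 of the 9 fits. Kl went from -3.42 to -4.67, Prnd from -5.60 to -6.46 and Katnal2 from 3.22 to 2.50 without aged vehicle library 1, and they passed in 2, 1 and 5 of the 9 fits. Every gene called had non-overlapping libraries, and over all genes tested 26.2% did not overlap, where chance gives 10%.

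**Figure D2:**
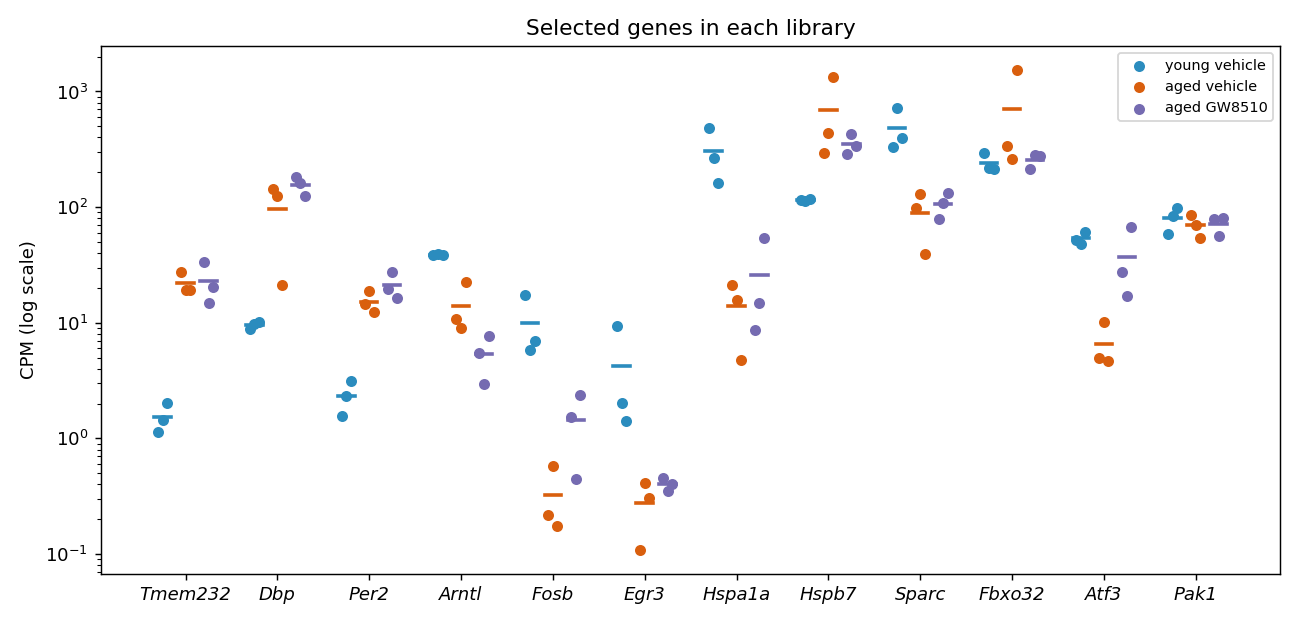
TMM-scaled CPM (log axis) of 12 genes in each library, where the points are libraries, short lines are group means (n = 3) and colours are the young vehicle, aged vehicle and aged GW8510 groups. Dbp and Fbxo32 show aged vehicle library 4 away from the other aged vehicle libraries, at 21.2 and 1536 CPM. Fbxo32 was chosen after its values were seen.

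Immediate-early genes, which are transcribed within minutes of a stimulus, were lower with age as a list. Of 24 members tested, 8 fell, none rose and 16 did not pass, and adjusted over the list alone 17 fell and 1 rose. The list passed (camera adjusted p = 1.18e-14, and adjusted p = 0.129 with an estimated correlation). Egr1, a zinc finger factor, fell 4.75-fold, Egr3, its relative, 15.5-fold, the shear-responsive factor Klf2 3.22-fold, and Ier2 2.51-fold. Without young vehicle library 2 the log2 fold change of Egr3 went from -3.95 to -2.65 and that of Fosb from -4.95 to -4.31, and Egr3 passed in 1 of the 9 fits without a library. Over these fits Fosb reached -5.64 at the other end. Atf3, a stress-induced AP-1 partner, stood at 6.57 ± 3.06 CPM in aged vehicle and 53.6 ± 6.79 CPM in young vehicle libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0306). Without aged vehicle library 4, 8 members fell and 21 fell adjusted over the list alone.

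Collagen and matrix genes were also lower as a list. Of 45 members, 7 fell, none rose and 38 did not pass, with a median log2 fold change of -1.92 and 38 lower adjusted over the list alone. The list passed (camera adjusted p = 3.95e-23, and adjusted p = 0.431 with an estimated correlation). Col14a1, a fibril-associated collagen gene, fell 9.60-fold, Thbs1, which encodes thrombospondin 1, 8.73-fold, and the basement membrane collagen gene Col4a2 3.78-fold. The log2 fold change of Thbs1 went from -3.13 to -3.99 without aged vehicle library 3. Aged vehicle library 4 held the lowest level of 39 of the 45 members, and its mean centred log2 level of the list was -1.92, against -0.50 and 0.06 in the other aged vehicle libraries and 0.93 to 1.56 in the young. Without that library 3 members fell, and 34 fell adjusted over the list alone.

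Of 5 lists that mark other cells of the tissue, single members fell in the fibroblast and tendon lists and none in the other 3. In the fibroblast list 1 of 15 members fell, the surface sialomucin gene Cd34 (2.09-fold), and 4 fell adjusted over the list alone (camera adjusted p = 1.70e-07, and adjusted p = 0.505 with an estimated correlation). In the tendon list 1 of 9 fell, the matrix gene Cilp2 (25.8-fold), and 7 fell adjusted over the list alone (camera adjusted p = 2.49e-06, and adjusted p = 0.431 with an estimated correlation). The log2 fold change of Cilp2, -4.69, was -3.90 without young vehicle library 3 and -5.48 without aged vehicle library 3. The endothelial list also passed as lower, with no member past the threshold and 4 of 19 lower adjusted over the list alone (camera adjusted p = 0.00266, and adjusted p = 0.598 with an estimated correlation). The smooth muscle (camera adjusted p = 0.00398, and adjusted p = 0.598 with an estimated correlation) and Schwann cell lists (camera adjusted p = 0.0125, and adjusted p = 0.637 with an estimated correlation) passed as lower with no member past the threshold, and both lost the call without aged vehicle library 4 (camera adjusted p = 0.103 and 0.217). That library had the lowest mean level of all 9 for all 5 of these lists, and without it no fibroblast member fell, the fibroblast mean being -1.89 and the tendon mean -2.51.

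Clock genes changed in opposite directions. Of 22 members, 4 rose (Per2, Per3, Nr1d2 and Dbp) and 1 fell, Npas2, a partner of the clock activator BMAL1. Adjusted over the list alone, 11 rose and 5 fell, and the list passed as higher (camera adjusted p = 0.00878, and adjusted p = 0.189 with an estimated correlation). Dbp, a clock-driven output factor, rose to 96.3 ± 65.6 against 9.56 ± 0.719 CPM, a 10.1-fold difference, and Npas2 fell 13.7-fold. Dbp measured 21.2 CPM in aged vehicle library 4, and 142 and 125 CPM in the other aged vehicle libraries. Without library 4, 6 members rose and 2 fell.

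Heat shock and chaperone genes divided, with 2 of 25 members higher, 4 lower and 19 not past the threshold. The inducible chaperone gene Hspa1a fell to 14.0 ± 8.39 against 303 ± 165 CPM, its near-identical neighbour Hspa1b fell 25.5-fold, and the collagen chaperone gene Serpinh1 fell 3.14-fold. The small heat shock genes Hspb6 and Hspb7, both abundant in muscle, rose 2.42-fold and 5.97-fold, with Hspb7 at 1336 CPM in aged vehicle library 4 and 294 and 436 CPM in the other aged vehicle libraries. Hspb6 passed in 0 of the 9 fits without a library. Without library 4 the log2 fold change of Hspb7 went from 2.58 to 1.66. The list as a whole did not pass in 1 direction (camera adjusted p = 0.102, and adjusted p = 0.598 with an estimated correlation), and adjusted over the list alone 3 members rose and 7 fell. By fry mixed, which tests for changes of either sign, the list passed (adjusted p = 0.00044). Without aged vehicle library 4, 1 member rose and 2 fell.

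Cytosolic ribosomal protein genes were higher as a list, with 76 of 78 log2 fold changes above 0 and a median of 0.47 (camera adjusted p = 1.54e-14, and adjusted p = 0.598 with an estimated correlation). The median was 0.29 without aged vehicle library 4, whose mean list level was 0.47 against -0.03 and 0.03 in the other aged vehicle libraries. A single member passed, Rpsa, a small subunit gene that rose 2.03-fold, and Rpsa passed in 1 of the 9 fits without a library. Rpsa summed with its pseudogene Rpsa-ps10, which measured 175 ± 94.9 CPM in young and 0 CPM in aged libraries, differed between all aged and young libraries by log2 0.27, against 1.04 for Rpsa alone. The pseudogene was read only in the young, where Rpsa was lower, so the smaller difference does not test sharing of reads. The mitochondrially encoded list (camera adjusted p = 0.0140, and adjusted p = 0.598 with an estimated correlation) and the fatty acid oxidation list (camera adjusted p = 0.0226, and adjusted p = 0.637 with an estimated correlation) passed as higher with no member past the threshold. The first lost its call without aged vehicle library 3 (camera adjusted p = 0.144), and the second without that library (0.115) or young vehicle library 2 (0.0614). Lists of the nuclear-encoded respiratory chain (camera adjusted p = 0.409, and adjusted p = 0.905 with an estimated correlation), citric acid cycle, glycolysis, slow fibre and fast fibre genes did not pass and held no member past the threshold.

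Proliferation genes fell as a list (camera adjusted p = 0.00103, and adjusted p = 0.129 with an estimated correlation), with 1 of 33 members lower, the cyclin-dependent kinase gene Cdk6 (3.56-fold), and 2 lower adjusted over the list alone (2 and 4 without aged vehicle library 4). The senescence and secretory list passed as lower with no member past the threshold (camera adjusted p = 0.0179, and adjusted p = 0.413 with an estimated correlation), a call lost without young vehicle library 2 (camera adjusted p = 0.0540), young vehicle library 3 (0.0570) or aged vehicle library 1 (0.0732). Among p53 targets 1 of 20 rose, the ectodysplasin A2 receptor gene Eda2r (8.44-fold), and the list did not pass (camera adjusted p = 0.443, and adjusted p = 0.637 with an estimated correlation). Eda2r measured 118 CPM in aged vehicle library 4 and 34.8 and 22.2 CPM in the other aged vehicle libraries, and without library 4 its log2 fold change went from 3.08 to 2.05. The antioxidant list passed as higher (camera adjusted p = 0.0179, and adjusted p = 0.482 with an estimated correlation), with 1 member up, the extracellular glutathione peroxidase gene Gpx3 (2.68-fold), and lost its call without young vehicle library 4 (camera adjusted p = 0.0589).

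Lists of muscle atrophy genes (camera adjusted p = 0.0399, and adjusted p = 0.598 with an estimated correlation) and of autophagy and lysosome genes (camera adjusted p = 0.00103, and adjusted p = 0.598 with an estimated correlation) passed as higher with no member past the threshold. Both lost the call without aged vehicle library 4 (camera adjusted p = 0.275 and 0.0525), where 17 of 30 atrophy members reached their highest level of all 9 libraries. The atrophy list also lost its call without young vehicle library 3 (0.0570), young vehicle library 4 (0.0818) or aged GW8510 library 4 (0.0508). Fbxo32 and Trim63, muscle ubiquitin ligase genes chosen after their values were seen, measured 1536 and 833 CPM there. In the other aged vehicle libraries Fbxo32 measured 339.9 and 260.1 CPM.

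Single members of lists that did not pass or were not tested were also called. The insulin signalling genes Irs2 and Igf1, a substrate of the insulin receptor and a growth factor, fell 2.52-fold and 3.73-fold. Trib3, a pseudokinase gene of the amino acid stress response, rose 4.23-fold, the cardiac actin gene Actc1 fell 21.4-fold, the atrial myosin light chain gene Myl4 rose 3.52-fold, the carbonic anhydrase gene Car3 fell 2.37-fold and Trp63, a p53 relative from a marker list too small to test, rose 2.18-fold. Actc1 went from a log2 fold change of -4.42 to -5.53 without aged vehicle library 3. Car3 passed in 0 of the 9 fits without a library. Lists of interferon response, glucocorticoid target, neuromuscular junction, p21-activated kinase pathway, satellite cell, macrophage, neutrophil and mast cell, B and plasma cell and erythroid genes did not pass by camera and held no member past the threshold. The erythroid list had a positive median (0.80) and mean while its camera direction was down, and the insulin list had a median of 0.05 and a mean of -0.01. Neither passed (camera adjusted p = 0.471 and 0.805). By fry, which tests whether genes move 1 way on balance, 4 lists passed: immediate-early (adjusted p = 0.00533), proliferation (0.00533), clock (0.00776) and satellite cell (0.0412). Some lists that camera did not call passed by fry mixed. These were heat shock (adjusted p = 0.00044), p53 target (0.000111), cardiac (0.000667), insulin (0.0326) and p21-activated kinase genes (0.0329).

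In all, 16 lists passed by camera with the preset correlation and none with an estimated correlation. No annotation term passed in 7082 tests among the genes called by edgeR, against 72 among the 974 genes called by DESeq2 and 18 among the 156 called by limma-voom, led in both by lower matrix and collagen terms. The count of 175 genes fell to 50 with only the 6 libraries compared and to 48, 19 and 48 without young vehicle library 2, 3 or 4, 40 without aged vehicle library 1 and 35 without aged GW8510 library 3. Without aged vehicle library 4 it was 143, of which 99 were shared. In the table the authors deposited, 653 genes were marked, 216 higher and 437 lower.

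**Figure D3:**
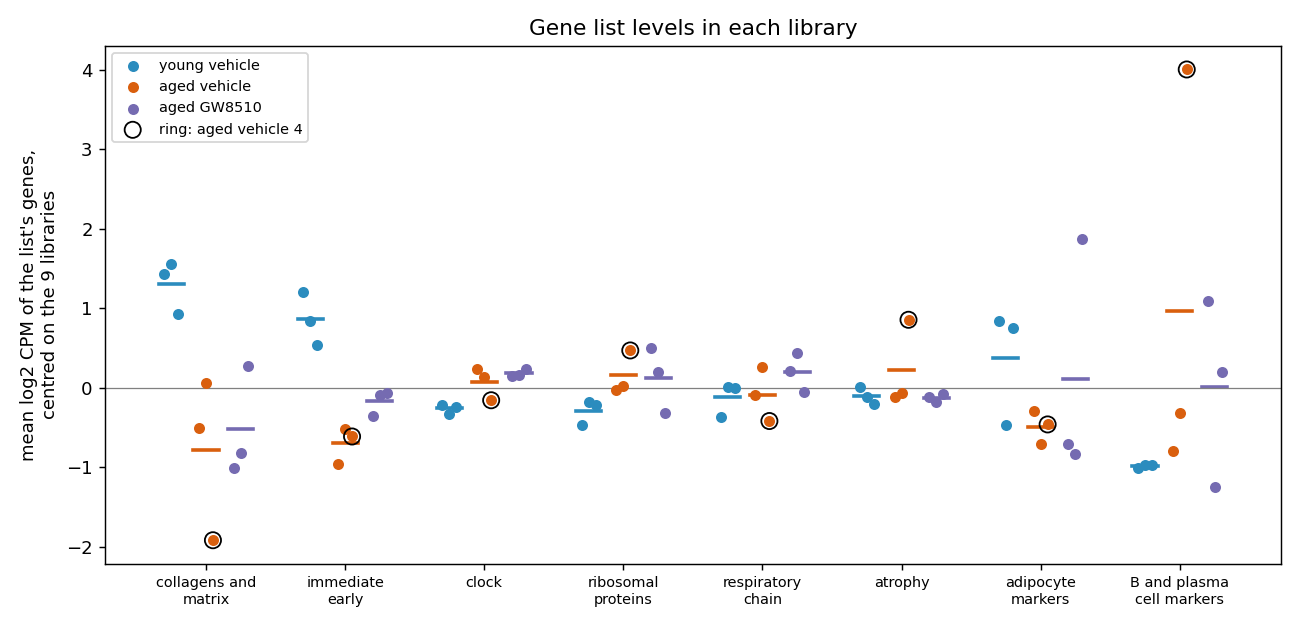
Mean log2 CPM of the genes of 8 lists in each library, centred on the 9 libraries, where the points are libraries, short lines are group means (n = 3) and the ring marks aged vehicle library 4. That library lies at -1.92 for collagens and matrix and at 4.01 for B and plasma cell markers, and aged GW8510 library 4 lies at 1.87 for adipocyte markers.

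The treatment comparison asked what 14 days of GW8510 changed in 18-month muscle. No gene of 14384 passed in edgeR's quasi-likelihood test, where the smallest adjusted p was 0.790. At an unadjusted p under 0.05 there were 647 genes, where 719 would be expected by chance. DESeq2 called 10 genes (8 higher and 2 lower), limma-voom none and edgeR without a filter 5. The same test recovered 91 of 100 genes changed 4-fold and 37 of 100 changed 2-fold in simulated counts of this comparison, all drawn from genes with a mean count of at least 50, so recovery of lower genes was not measured. Simulations with the same dispersions and the age means called 1291 genes with age on average, against 175 in the data. They took the measured means, noise included, as true, so this gap does not measure recovery. Recovery in the data was not measured and may be lower than in simulated counts.

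The 10 genes with the smallest p, none past the threshold in edgeR, included Atf3 (ENSMUSG00000026628, chromosome 1 from 191170296 to 191218039, protein coding), the stress-induced AP-1 partner, which fell with age. Atf3 measured 27.4, 16.9 and 67.3 CPM in the GW8510 libraries and 4.95, 10.1 and 4.68 CPM in aged vehicle libraries. Its log2 difference was 2.50 with a standard error of 0.49 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.934), against an adjusted p of 0.000206 by DESeq2 and 0.0359 by edgeR with no filter. Without aged GW8510 library 4 the difference was 1.74. Sox7, an endothelial transcription factor gene, stood at 17.3 ± 4.25 against 6.84 ± 1.49 CPM in aged vehicle libraries, and Sntb1, which encodes the dystrophin-associated protein syntrophin beta 1, at 4.04 ± 0.159 against 1.56 ± 0.399 CPM. Ifrd1, a regulator of muscle differentiation and repair, measured 76.7 ± 12.9 against 43.0 ± 6.96 CPM, Car3 705 ± 142 against 354 ± 45.4 CPM and Trp63 11.4 ± 0.707 against 21.2 ± 4.78 CPM. Snai3, Chtf8, the antisense gene AC157910.6 and A530016L24Rik complete the 10. Of these 10, DESeq2 called Atf3, Sox7, Sntb1, Ifrd1, Car3, Trp63, AC157910.6 and A530016L24Rik.

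The 5 genes called without a filter were Atf3, Chtf8, AC157910.6, A530016L24Rik and Gm10031, the last of which was chosen after its values were seen. Leaving out aged vehicle library 3 gave 2 calls, Gm10031 and Gm20388, both lower and both chosen in the same way, and leaving out any other library gave none. Gm20388 measured 93.9 ± 40.9 CPM in the GW8510 and 1176 ± 961 CPM in the aged vehicle libraries. The authors' own test marked 6 genes, all higher: Atf3, Sox7, Chtf8, AC157910.6, A530016L24Rik and the pseudogene Gm4294. Over all genes 1038 (7.22%) did not overlap between the groups, where chance gives 10%.

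Among gene lists, 4 of mitochondrial energy metabolism were higher in GW8510 libraries as sets, while the glycolysis and glycogen list did not pass (camera adjusted p = 0.103, and adjusted p = 0.671 with an estimated correlation). All 76 members of the nuclear-encoded respiratory chain list had log2 differences above 0, with a median of 0.27 and none past the threshold over all genes or adjusted over the list alone (camera adjusted p = 5.69e-12, and adjusted p = 0.671 with an estimated correlation). The estimated correlation between these members was 0.796, so their shared sign does not count as 76 independent observations. The citric acid cycle list (camera adjusted p = 0.000148, and adjusted p = 0.671 with an estimated correlation), mitochondrially encoded list (camera adjusted p = 0.00335, and adjusted p = 0.671 with an estimated correlation) and fatty acid oxidation list (camera adjusted p = 0.000108, and adjusted p = 0.671 with an estimated correlation) passed as higher in the same way, with no member called. Without aged vehicle library 4 the respiratory chain (camera adjusted p = 0.00145), citric acid cycle (0.0378) and fatty acid oxidation (4.92e-07) lists still passed and the mitochondrially encoded list did not (0.0709). With an estimated correlation all 4 had a camera adjusted p of 0.808 in that fit. The median of the respiratory chain list was then 0.12, and its mean difference in log2 CPM went from 0.29 to 0.11, that of the citric acid cycle list from 0.25 to 0.12. Without aged GW8510 library 3 the mitochondrially encoded (0.103) and fatty acid oxidation (0.608) lists did not pass. The mean respiratory chain level was -0.42 in aged vehicle library 4, the lowest of the 9 libraries.

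The slow fibre list passed as higher (camera adjusted p = 0.00598, and adjusted p = 0.671 with an estimated correlation), with 14 of 15 log2 differences above 0 and no member past the threshold. Aged GW8510 library 3 held the highest level of 12 of the 15 members, and without it the list did not pass (camera adjusted p = 0.682), nor without aged vehicle library 1 (0.174). Myh7, the slow myosin heavy chain gene chosen after its values were seen, measured 23.0 CPM in that library and 4.99 and 1.78 CPM in the other GW8510 libraries. The adipocyte list passed as higher (camera adjusted p = 0.000624, and adjusted p = 0.671 with an estimated correlation), with 4 of 15 members higher adjusted over the list alone and none over all genes. Aged GW8510 library 4 held the highest level of 8 of the 15, with Adipoq, the adiponectin gene chosen after its values were seen, at 18.7 CPM against 1.41 and 0.531 CPM in the other GW8510 libraries, and without it the list did not pass (camera adjusted p = 0.936), its mean difference being -0.30 with camera direction up.

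Endothelial (camera adjusted p = 1.46e-07, and adjusted p = 0.671 with an estimated correlation) and immediate-early genes (camera adjusted p = 2.24e-05, and adjusted p = 0.671 with an estimated correlation) were higher as lists in each of the 9 fits that left out 1 library, with no endothelial member and 1 immediate-early member past the threshold adjusted over the list alone. Smooth muscle (camera adjusted p = 0.000152, and adjusted p = 0.671 with an estimated correlation), fibroblast (camera adjusted p = 0.00335, and adjusted p = 0.671 with an estimated correlation) and collagen and matrix genes (camera adjusted p = 0.0440, and adjusted p = 0.888 with an estimated correlation) passed as higher with no member called. Without aged vehicle library 4, which held the lowest mean levels of these lists, the smooth muscle (camera adjusted p = 0.114) and fibroblast (0.767) lists did not pass. The collagen list then passed as lower (camera adjusted p = 0.00145, and adjusted p = 0.808 with an estimated correlation), with a mean difference of -0.31 in log2 CPM. Without aged GW8510 library 4 the fibroblast list did not pass (0.237), and the mean difference of the collagen list was -0.14 in log2 CPM (camera adjusted p = 0.242).

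Atrophy (camera adjusted p = 0.000523, and adjusted p = 0.671 with an estimated correlation), autophagy (camera adjusted p = 0.00335, and adjusted p = 0.671 with an estimated correlation) and interferon response genes (camera adjusted p = 0.00901, and adjusted p = 0.671 with an estimated correlation) passed as lower, with no member called. None of the 3 passed without aged vehicle library 4 (camera adjusted p = 0.405, 0.623 and 0.623), whose mean levels of the atrophy and autophagy lists were 0.86 and 0.45, the highest of the 9 libraries. Without aged GW8510 library 4 the autophagy (0.0689) and interferon (0.564) lists did not pass, nor did the interferon list without aged GW8510 library 1 (0.0863). The other 22 lists, clock (camera adjusted p = 0.477, and adjusted p = 0.671 with an estimated correlation), ribosomal protein, proliferation, heat shock and p53 target genes among them, did not pass, and among them the p53 target, senescence, ribosomal protein, p21-activated kinase, antioxidant and proliferation lists had medians and means of different sign, while the cardiac list had both below 0 with camera direction up. With no gene called, annotation terms were not tested. Of the 14 lists that passed, none passed with an estimated correlation or by fry in 1 direction or mixed.

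The p21-activated kinase genes, named in the series title, were measured as Pak1, Pak2 and Pak4, and the other 3 family members were too low to test. Pak1, a kinase activated by the small GTPases Rac1 and Cdc42, stood at 71.8 ± 13.4 CPM in GW8510, 69.8 ± 15.5 CPM in aged vehicle and 80.1 ± 20.3 CPM in young vehicle libraries (SD, n = 3 each). Pak2 stood at 23.4 ± 3.07, 23.4 ± 0.795 and 27.4 ± 3.20 CPM, and Pak4 at 2.55 ± 0.644, 2.68 ± 0.281 and 3.21 ± 0.102 CPM. None passed in any of the 3 comparisons, the smallest adjusted p being 0.417 for Pak2 with age (edgeR quasi-likelihood, Benjamini-Hochberg), nor under any alternative. The list of these kinases, their activators and substrates did not pass in the age (camera adjusted p = 0.183, and adjusted p = 0.598 with an estimated correlation), treatment (camera adjusted p = 0.819, and adjusted p = 0.954 with an estimated correlation) or last comparison (camera adjusted p = 0.244, and adjusted p = 0.592 with an estimated correlation), with no member called. By fry mixed the list passed with age (adjusted p = 0.0329) and not in the treatment (0.824) or last comparison (0.0630).

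Genes called with age were then followed in the treatment comparison. Of the 175 age genes, 126 (72%, exact 95% interval 64.7% to 78.5%) had a treatment difference of the opposite sign. Because the aged vehicle libraries enter both contrasts, simulated data with the age effect and no treatment effect gave 67.6% on average, from 65.0% to 70.8% over 20 simulations. The observed share lay above that range, but these simulations called 1291 genes with age on average, more than the data, so the selection is not matched. Where the age genes were chosen without 1 aged vehicle library and the treatment difference was measured against that library alone, the share was 32.5% (13 of 40), 40.8% (60 of 147) and 54.5% (78 of 143) for libraries 1, 3 and 4. Over all genes the correlation of the age and treatment log2 fold changes was -0.367 (Spearman -0.394), where simulations with an age effect and no treatment effect gave -0.249 and simulations with no effect at all -0.498. The simulations with an age effect took the measured group means as true, so noise in those means counted as age effect. Their -0.249 is therefore not a matched expectation, and the difference from the data cannot be read as a treatment effect. The covariance was -0.110 against a simulated -0.0820, and -0.118 from the spread of the aged vehicle libraries alone. Genes are not independent replicates.

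Among the age genes, Atf3 and Car3, which fell with age, and Trp63, which rose, lay the other way in GW8510 libraries, and none of the 3 passed in the treatment comparison. The share of opposite signs was 51.0% without aged vehicle library 4, with a correlation of -0.222, and 85.1% without aged vehicle library 3, with a correlation of -0.553. It was 36.8% without young vehicle library 3. Without aged GW8510 library 4 the correlation was -0.189.

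**Figure D4:**
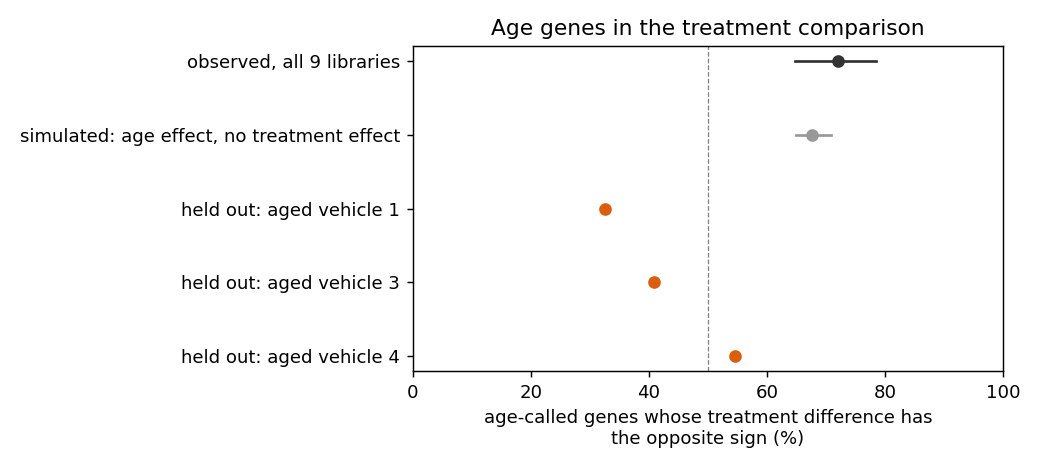
Percent of age-called genes whose treatment difference has the opposite sign, for all 9 libraries (72%, line: exact 95% interval), for simulated data with an age effect and no treatment effect (mean of 20 simulations, line: range), and for age genes chosen without 1 aged vehicle library with the treatment difference measured against that library. The dashed line marks 50%.

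The last comparison set GW8510-treated 18-month muscle against 2-month vehicle muscle, the outer groups of the design. Of 14384 genes, 48 rose and 60 fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Dbp, the clock output factor, rose to 156 ± 29.2 against 9.56 ± 0.719 CPM in the young (SD, n = 3 each), a 16.4-fold difference. Arntl, which encodes the clock activator BMAL1, fell 7.21-fold, and Per2 rose 9.04-fold. The stress co-chaperone gene Dnajb1 fell 8.20-fold and the cardiac actin gene Actc1 40.2-fold.

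Tmem232 rose to 22.9 ± 9.50 against 1.53 ± 0.457 CPM, with a log2 fold change of 3.90 and a standard error of 0.36 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00168). Of 29 named genes past the threshold, Tmem232, Per2, Per3, Dnajb1 and Zfp968 (ENSMUSG00000078898, chromosome 2 from 175372436 to 175384201, protein coding) were the 5 that passed in each of the 9 fits without 1 library. With the replicate number as a block, Tmem232 and Zfp968 still passed and Per2, Per3 and Dnajb1 did not. Zfp968 and Zfp973, zinc finger genes of chromosome 2, fell 12.3-fold and 7.09-fold. Further falls were in Igf2bp2, an RNA-binding protein gene (14.8-fold), Kcnf1, a potassium channel subunit gene (13.2-fold), Tsga10ip (18.3-fold) and Igsf9b, a synaptic adhesion gene (9.30-fold). Without young vehicle library 4 the log2 fold change of Kcnf1 went from -3.72 to -3.05 and that of Tsga10ip from -4.19 to -3.61, and without aged GW8510 library 1 that of Igf2bp2 went from -3.89 to -4.70. Rises were in Katnal2 (7.53-fold), Nxpe3 (6.57-fold), Amy1 (5.58-fold), Irak1bp1 (4.99-fold), Trib3 (6.26-fold) and Ahr, the aryl hydrocarbon receptor gene (4.51-fold).

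In the clock list 6 of 22 members rose, Per2, Per3, Nr1d2, Dbp, Cry2 and Ciart, 1 fell, Arntl, and 15 did not pass, while adjusted over the list alone 10 rose and 5 fell (camera adjusted p = 0.00268, and adjusted p = 0.192 with an estimated correlation). Ciart, a clock repressor, rose 9.29-fold, and Arntl stood at 5.36 ± 2.33 against 38.7 ± 0.443 CPM. Cry2, another repressor, was named after its values were seen. The clock genes called were 9 higher and 3 lower without aged vehicle library 4, which is in neither group compared here. Among annotation terms, 4 of 7082 tests passed, all on higher genes: rhythmic process (6 of 99 tested members called, adjusted p = 0.00201), circadian regulation of gene expression (5 of 53, 0.00201), circadian rhythm (5 of 66, 0.00304) and sequence-specific binding of regulatory DNA (5 of 60, 0.00251), by 1-sided Fisher exact tests. All 4 held Ciart, Cry2 and Per3, so they overlap. None passed with library totals in place of TMM factors, or without young vehicle library 3, aged vehicle library 1 or aged GW8510 library 1 or 3. Without young vehicle library 2, 2 passed, and 36 passed without aged vehicle library 4.

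Collagen and matrix genes and immediate-early genes were lower than in the young as lists by camera with the preset correlation. Of 45 collagen and matrix genes 1 fell, the collagen cross-linking enzyme gene Lox (3.27-fold), and 31 fell adjusted over the list alone, with a median log2 fold change of -1.67 (camera adjusted p = 1.35e-20, and adjusted p = 0.358 with an estimated correlation). Without aged vehicle library 4, 24 fell. Fibroblast (camera adjusted p = 0.000178, and adjusted p = 0.523 with an estimated correlation) and tendon lists (camera adjusted p = 3.66e-06, and adjusted p = 0.358 with an estimated correlation) passed as lower, the tendon gene Cilp2 falling 39.8-fold. The log2 fold change of Cilp2, -5.31, was -4.52 without young vehicle library 3 and -6.38 without aged GW8510 library 4. In the immediate-early list 2 of 24 fell, Egr1 (3.48-fold) and Fosl2, an AP-1 component (3.63-fold), and adjusted over the list alone 12 fell and 1 rose (camera adjusted p = 3.47e-09, and adjusted p = 0.196 with an estimated correlation). With aged vehicle library 4 left out, 9 immediate-early genes and 3 tendon genes were lower. Proliferation (camera adjusted p = 0.000599, and adjusted p = 0.192 with an estimated correlation), heat shock (camera adjusted p = 0.00336, and adjusted p = 0.358 with an estimated correlation), interferon (camera adjusted p = 0.000178, and adjusted p = 0.523 with an estimated correlation), satellite cell (camera adjusted p = 0.00840, and adjusted p = 0.196 with an estimated correlation) and Schwann cell lists (camera adjusted p = 0.0277, and adjusted p = 0.722 with an estimated correlation) also passed as lower. Cdk6 (3.87-fold) and Dnajb1 were the members called. When aged vehicle library 4 was left out, 4 proliferation genes, 6 heat shock genes, 1 interferon gene and 1 satellite cell gene were lower and 2 heat shock genes higher. The Schwann list lost its call without young vehicle library 2 (camera adjusted p = 0.0919) or aged GW8510 library 1 (0.200).

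Lists of mitochondrial energy metabolism were higher than in the young. Of 35 fatty acid oxidation genes none passed over all genes, and adjusted over the list alone 13 rose and 1 fell (camera adjusted p = 6.03e-07, and adjusted p = 0.461 with an estimated correlation). Of 12 mitochondrially encoded genes 8 rose adjusted over the list alone (camera adjusted p = 9.82e-06, and adjusted p = 0.358 with an estimated correlation). These counts over all genes were 1 and 3 without aged vehicle library 4, and the citric acid cycle, slow fibre, antioxidant and glycolysis lists then held 2, 1, 2 and 4 higher members. In the citric acid cycle list the mitochondrial isocitrate dehydrogenase gene Idh2 rose 3.38-fold (camera adjusted p = 0.00812, and adjusted p = 0.627 with an estimated correlation), and the list lost its call without young vehicle library 2 (camera adjusted p = 0.139) or aged GW8510 library 3 (0.0556). Respiratory chain (camera adjusted p = 1.62e-08, and adjusted p = 0.622 with an estimated correlation), ribosomal protein (camera adjusted p = 2.20e-13, and adjusted p = 0.523 with an estimated correlation) and slow fibre lists (camera adjusted p = 0.00192, and adjusted p = 0.523 with an estimated correlation) passed as higher with no member called, the slow fibre list not without aged GW8510 library 3 (camera adjusted p = 0.0957). The antioxidant list passed as higher with Gpx3 up by 1.58 on the log2 scale (camera adjusted p = 0.00943, and adjusted p = 0.358 with an estimated correlation). Pparg, the master regulator of adipocytes, rose 3.36-fold in an adipocyte list that did not pass (camera adjusted p = 0.821, and adjusted p = 0.968 with an estimated correlation). The other 18 lists did not pass by camera, those of atrophy, autophagy, glycolysis, fast fibre, senescence, p53 target, endothelial, smooth muscle, macrophage and erythroid genes among them. The erythroid list had a positive median and mean with camera direction down, and the insulin, glycolysis and atrophy lists had medians and means of different sign. By fry in 1 direction 4 lists passed, clock (adjusted p = 0.00692), proliferation (0.00967), satellite cell (0.0148) and immediate-early (0.0248). By fry mixed the p53 target (adjusted p = 0.000337), amino acid stress (0.0136) and cardiac lists (0.00295) passed, which camera did not call.

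Both comparisons against the young shared 27 higher genes and 38 lower genes. Independent lists of these sizes would share 0.25 and 0.417 genes, an expectation that leaves out the shared young libraries. The log2 fold changes correlated at 0.827 over genes, with a covariance of 0.409. Simulated unchanged groups gave 0.497 and 0.0812, and simulations with an age effect and no treatment effect gave 0.871 (0.862 to 0.877) and 0.557 (0.542 to 0.573), both above the data. The simulations with an age effect called 1291 and 1270 genes on average, against 175 and 108, so they are not matched to the data. Part of the excess may come from the shared young libraries, which are too few to divide. With library totals in place of TMM factors the calls were 43 higher and 82 lower. The count of 108 moved to 469 with only the 6 libraries compared and to 594 without aged vehicle library 4. That library is in neither group compared here, so leaving it out acts through the pooled spread, the gene filter and the scaling. The count fell to 63, 27 and 42 without young vehicle library 2, 3 or 4 and to 38 and 25 without aged GW8510 library 1 or 3. The authors' table marked 729 genes, 300 higher and 429 lower.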

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

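The term counts under other settings, the DESeq2 fit on the 6 libraries with no filter and the protein-coding fit were chosen after seeing the data, and the other alternatives were fixed beforehand. Among the counts and shares that answer a comparison, 117 of the alternative values kept their side of the threshold or stayed within 1.5 times, while 15 shares or correlations moved, and 24 values were stronger and 26 weaker, and the cause of the changes below was not tested unless stated. For single genes and lists, 1754 values stayed the same, 497 lost and 17 gained the threshold, and 5 reversed.

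For aged over young vehicle, 175 genes became 974 by DESeq2, 699 with no filter, 842 by DESeq2 on the 6 libraries with no filter and 50 with only the 6 libraries compared (other settings besides the block below 137 to 172), and 19 to 148 when 1 library was left out, the lowest without young vehicle 3 and the highest without aged vehicle 3. For the treatment, 0 genes became 10 by DESeq2, 5 with no filter and 6 by DESeq2 on the 6 libraries with no filter, and 0 to 2 when 1 library was left out. For aged GW8510 over young vehicle, 108 became 870, 553, 469 and 1268 by DESeq2, with no filter, with only the 6 libraries and by DESeq2 on those with no filter, and 25 to 594 when 1 library was left out, the lowest without aged GW8510 3 and the highest without aged vehicle 4. Aged vehicle 4 is in neither group of that comparison and acts there through the pooled spread, the gene filter and the scaling. DESeq2 called more unchanged genes in simulated counts (39, 38 and 31 against 6, 7 and 6). No p21-activated kinase was called under any alternative (0 in each fit without 1 library).

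Lists past the threshold fell from 16, 14 and 17 to 0, 0 and 0 with an estimated correlation and to 4, 0 and 4 by fry in 1 direction, and fry mixed gave 12, 0 and 12. Leaving out 1 library gave 15 to 22, 11 to 18 and 16 to 20. In the treatment comparison without aged vehicle 4 the mean log2 differences of the autophagy, collagen, interferon and fibroblast lists reversed to 0.0166, -0.308, 0.0356 and -0.0645, and without aged GW8510 4 that of the collagen list to -0.139. Over all fits without 1 library these 4 reached -0.220 and 0.688 without aged vehicle 3 (autophagy, collagen), -0.396 without aged GW8510 3 (interferon) and 0.973 without aged vehicle 3 (fibroblast) at the other end. Terms past the threshold went from 0 to 72, 18, 87 and 1 for age (DESeq2, limma-voom, no filter, 6 libraries), and 0 to 7 when 1 library was left out. For aged GW8510 over young vehicle they went from 4 to 0 with library totals, 38, 42 and 32 by DESeq2, no filter and 6 libraries, and 0 to 36 when 1 library was left out.

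The share of age genes of opposite sign, 72%, was 32.5%, 40.8% and 54.5% with aged vehicle 1, 3 or 4 held out, and 36.8% to 85.1% when 1 library was left out, where the correlation ran from -0.553 to -0.189. The replicate numbers give no sign of pairing: deviations of same-numbered libraries correlated at -0.0381 on average over 7 pairs and those of the 20 other pairs at 0.0134. With the replicate number as a block, 5 genes were called for age, 0 for the treatment and 8 for aged GW8510 over young vehicle, the opposite share was 20% of those 5, and lists past the threshold numbered 17, 13 and 19. The pseudocount and filter for normalized values were not run because counts were used. Depth of 21718930 to 27437937 counts sets a floor of 0.109 to 0.138 CPM, below which no level can be given.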

Other observations

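Besides the splits of the libraries, which were fixed beforehand, the tests in this part were chosen after the results were seen. Aged vehicle library 4 differed from the other aged libraries in groups of genes not described so far, all chosen after their values were seen. Igkc and Jchain, which encode the immunoglobulin kappa constant region and the joining chain of secreted antibodies, measured 156 and 15.9 CPM in that library. Igkc reached 5.31 CPM at most in the other 8 libraries, and the B and plasma cell list had a mean centred log2 level of 4.01 in library 4. The metallothionein gene Mt2, a metal-binding stress gene, measured 249.5 CPM there against 2.15 and 14.6 CPM in the other aged vehicle libraries, and the glucocorticoid target list stood at 1.32. The haemoglobin gene Hba-a1, a marker of blood in the tissue, measured 196 and 259 CPM in aged vehicle library 1 and aged GW8510 library 3, and 1.95 CPM in aged GW8510 library 1.

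Clock genes differed between young and aged vehicle libraries. Without aged vehicle library 4, 8 clock genes still passed. The mean clock list level was -0.16 in that library and 0.24 and 0.14 in the other aged vehicle libraries, against -0.33 to -0.21 in the young. Library 4 thus lay nearest the young, so leaving it out was likely to keep the calls. These levels argue against that library alone as the cause. If tissue had been collected at different times of day, the activator side (Arntl, Clock, Npas2 and Nfil3) would move against the output genes, and 87.5% of 16 measured members (14) followed this. An age-related change of the clock stays open as well, because 0 libraries carry a collection time in the labels, so these explanations cannot be told apart. A difference in time of day between the groups may account for part of the clock calls.

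A set of 14 genes was read in all libraries of 1 age (at least 0.5 CPM, here on library totals with no TMM) and in none of the other (at most 0.15 CPM), 8 in the 3 young and 6 in the 6 aged libraries, and the highest count among the other splits of 3 against 6 libraries was 2, over 84 splits in all. Pseudogenes made up 50% of them, against 2.81% of tested genes, and Rpsa-ps10 measured 175 ± 94.9 CPM in young and 0 CPM in aged libraries. A candidate explanation is a stock variant that differs between the young and aged mice, which this share fits. Reads shared with parent genes stay open: in 2 of 3 pseudogenes the sum with the parent differed less between the ages than the parent alone, but all 3 parents are higher in aged libraries, so this follows from which age holds the pseudogene and does not test sharing. A switch of genes with age stays open: 28.6% of the 14 are protein coding, a share that does not test a switch. These explanations cannot be told apart by the present samples. They may also bear on the calls against the young, where pseudogenes were 13 of 175 (aged vehicle) and 9 of 108 (aged GW8510).

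Gene lists moved between GW8510 and aged vehicle libraries by camera with the preset correlation. Of the 3 lower lists 0 stayed past the threshold in the same direction without aged vehicle library 4, so these lower lists may rest on that library. Of the 11 higher lists 7 stayed at the preset correlation. With an estimated correlation these 7 each had a camera adjusted p of 0.808 in that fit, so the test cannot decide whether they rest on that library. The mean difference of the respiratory chain list fell from 0.29 to 0.11 and that of the citric acid cycle list from 0.25 to 0.12. Of the 7, the fatty acid oxidation and slow fibre lists lost the call without aged GW8510 library 3 (camera adjusted p = 0.608 and 0.682), and the adipocyte list without aged GW8510 library 4 (0.936). An effect of GW8510 on the higher lists stays open, because the smallest adjusted p by camera with an estimated correlation was 0.671. In simulated counts of this comparison a list of 40 genes raised 2-fold or 4-fold was detected (camera p = 6.01e-07 with an estimated correlation). Those genes were drawn independently, so detection of small differences in lists as correlated as these was not measured.

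The 6 libraries of each comparison allow 10 splits into 3 and 3, too few for a share under 0.05. For aged over young vehicle the real split gave 175 genes, the highest of the others 2, and 1 split of 10 gave as many as the real one. For the treatment the real split gave 0 genes and the highest of the others 1, so all 10 gave as many by definition and the count tests nothing. At an unadjusted p under 0.05 the real split gave 647 genes and the others 400 to 1913. By that measure 6 of the 10 splits gave at least as many as the real one. For aged GW8510 over young vehicle the real split gave 108 genes and the highest of the others 0, so 1 of 10 gave as many.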
